A study of Homo sapiens with 8 samples.

How the data were processed

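RNA was measured in U-937 cells after 72 h with vehicle (PBS and DMSO), 250 µM LAA, 1 µM ATRA or both, in 8 libraries, 2 per group. Per the labels, mRNA was enriched with poly-T beads and libraries were made with an NEBNext Ultra II kit. The authors' processing notes name Salmon 1.8.0 and DESeq2 1.36.0 and the builds GRCh38 and hg38, while the annotation release, the index, the strand setting and the way transcripts were summed to genes are not given in the sources used here. The deposited estimated counts are Salmon's read counts per Ensembl gene, not scaled between libraries by the authors, with decimals. The deposited FPKM values were made by the authors from the same genes, per kilobase and scaled to library size, with a gene length that differed between libraries, and the scaling behind them is not stated. The count table listed 61125 genes, of which 99 identifiers were not matched to a symbol. Symbols, transcript lengths, GC content and positions came from GENCODE 29 on GRCh38, a reference chosen here that may differ from the authors' annotation.

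Estimated counts were rounded to whole numbers, which changed 16.5% of the values. Library totals were 19646442 and 19541981 in vehicle, 18536456 and 24166770 with ATRA, 19376377 and 18462552 with LAA, and 19294594 and 20749058 with LAA+ATRA. Genes with low counts were removed with filterByExpr in edgeR 4.0.16 under R 4.3.3, which left 14995 genes, 13791 of them with a symbol. Libraries were scaled by TMM. A quasi-likelihood negative binomial model with 4 group means was fitted to all 8 libraries, since 2 libraries per group leave little information on spread in any 1 group. It had 4 residual degrees of freedom, 8.2 prior degrees of freedom and a common dispersion of 0.0124. The 6 comparisons were ATRA, LAA and LAA+ATRA each against vehicle, LAA+ATRA against ATRA, LAA+ATRA against LAA, and the interaction, which is LAA+ATRA minus ATRA minus LAA plus vehicle on the log2 scale. P-values were two-sided from the edgeR quasi-likelihood F test, adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Where a group had no counts, the fold was bounded with a floor of 3 counts over the group, and its standard error is not given.

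Gene lists, 27 in all, were tested with camera in limma 3.58.1 on log2 CPM with voom weights and a preset correlation of 0.01 between genes, adjusted over the lists of each comparison. They were retinoid response, monocyte and macrophage markers, neutrophil and granulocyte markers, NADPH oxidase, myeloid transcription factors, myeloid progenitor and primary granule genes, TET and DNA methylation enzymes, ascorbate transport and recycling, NRF2 antioxidant targets, hypoxia and HIF targets, iron handling, G2 and mitosis, DNA replication, cell cycle inhibitors and G1, apoptosis regulators, interferon-stimulated genes, antigen presentation, cytokines and chemokines, adhesion and migration receptors, MYC targets and ribosome biogenesis, cholesterol synthesis, lipid efflux and LXR targets, unfolded protein and amino acid stress, glycolysis, oxidative phosphorylation, mitochondrially encoded transcripts and markers of other lineages. Some genes stand in more than 1 list. The lists, the tests of the 6 comparisons, the rule for named genes and the alternatives other than the length and GC correction were fixed before the data were examined. The tests on transcript length, on summed copies of a gene, on library size and on the size of the ATRA response were chosen afterwards. Genes were named by that rule. For each comparison it takes the 6 largest rises and the 6 largest falls with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and both libraries of 1 group above both of the other, the last condition not for the interaction. It adds up to 4 called members of each list by adjusted p, or the 2 most abundant members where none was called, and in every comparison TET1, TET2, TET3, RARA, RARB, CYP26A1, ITGAM, CD38 and SLC23A2. The text names a part of the genes so chosen.

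Alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2-style size factors (RLE) in place of TMM, no low-count filter, the replicate number as a block, a fit to only the libraries compared, limma on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with a mean of at least 1 FPKM in a group, and leaving out each library in turn, where the lone library left in a group is assumed to vary like the other groups. Lists were also tested with camera and an estimated correlation and with fry. After the data were seen, an alternative with per-library offsets for transcript length and GC content was added. Replicate numbers carry no stated meaning, so replicates were not paired. The effect of each compound with and without the other was compared by Pearson's and Spearman's correlation across genes and by the overlap of calls. Slopes on transcript length were compared by exact permutation over 70 splits.

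The procedure was tested on simulated data at the observed depth, with 200 genes changed in 1 group. These were drawn from genes with a mean of at least 5 CPM in vehicle, so the shares recovered do not cover genes with fewer counts. Of genes changed 2-fold, 92.5% were recovered for ATRA against vehicle, 92.5% for LAA against vehicle, 94% for LAA+ATRA against vehicle and against ATRA, 89.6% for LAA+ATRA against LAA and 71.6% for the interaction. At 1.5-fold the shares were 59.7%, 65.7%, 49.3%, 38.8%, 43.3% and 8.96%. Calls among unchanged genes numbered 25, 12, 21, 8, 11 and 10. For ATRA against vehicle the 25 stood beside 40, 62 and 66 recovered genes changed 1.5-fold, 2-fold and 4-fold. Except for LAA+ATRA against ATRA, unchanged genes made up a larger share of the calls than the adjusted p threshold allows. The threshold was therefore not fully held in these simulations. When 1 list was changed 1.3-fold, camera called it with adjusted p = 4.94e-35 and called 2 other lists, both of which share members with it. Genes varied independently of each other in these simulations. They therefore cannot show how often camera calls an unchanged list whose members move together. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 5.02 in vehicle, 19.7 with ATRA, 5.57 with LAA and 21.8 with LAA+ATRA. Genes too low to test, among them list members listed at 0 in every library, were left out of the tests. No group has more than 2 libraries, so permuting the libraries of a comparison was not used as a test.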

Results

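The data were RNA-sequencing estimated counts from U-937 cells, a human pro-monocytic leukemia line, treated for 72 h. The groups were vehicle, 250 µM L-ascorbic acid (LAA), 1 µM all-trans retinoic acid (ATRA, a retinoid that drives myeloid differentiation) and both compounds (LAA+ATRA), with 2 libraries per group and 8 in all. The comparisons ask what each compound does alone, what LAA adds in the presence of ATRA, and whether the effect of the pair differs from the sum of the single effects. Library totals ran from 18462552 estimated counts in LAA replicate 2 to 24166770 in ATRA replicate 2. The 10 most abundant genes took from 6.08% to 11.6% of a library. On the first principal component, which held 60.7% of the variance, the libraries with ATRA lay apart from those without it. The second component held 10.4%, and there the libraries with LAA scored from -28.3 to -17.1 and those without it from 12.5 to 29.9. Nothing in the labels says that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical. Group means are normalised read counts scaled to library size (CPM), given as mean ± SD with n = 2, and log2 fold changes as estimate ± standard error. A gene or list is called at an adjusted p under 0.05. For each called gene named below by its symbol, both libraries of 1 group lay above both of the other.

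ATRA changed the expression of a large part of the genes tested, and the largest rises were in genes silent or nearly silent in vehicle. CD38, a surface ADP-ribosyl cyclase and retinoid target, rose from 1.91 ± 0.318 CPM to 240 ± 17.9 CPM (log2 fold change 6.97 ± 0.16, adjusted p = 1.28e-10). TGM2, which encodes transglutaminase 2, had no counts in either vehicle library and 150 ± 29.6 CPM with ATRA, at least 2060-fold higher (adjusted p = 1.76e-09). DAAM2 (a formin-related actin regulator), SIGLEC11 (a sialic-acid receptor) and PTGES (prostaglandin E synthase) had no vehicle counts either, and were at least 864-fold, 313-fold and 117-fold higher. HIC1, a transcriptional repressor, rose from 0.604 ± 0.106 to 130 ± 34.5 CPM (log2 fold change 7.73 ± 0.27). ITGAM, the CD11b integrin chain of mature myeloid cells, rose from 10.8 ± 0.948 to 138 ± 22.7 CPM (log2 fold change 3.67 ± 0.15, adjusted p = 5.15e-09). Among the falls, IGLL1 (a surrogate light chain) went from 42.4 ± 3.08 to 0.311 ± 0.0486 CPM (log2 fold change -7.05 ± 0.31), and PDYN (prodynorphin) from 7.71 ± 0.06 to 0.437 ± 0.00773 CPM (-4.12 ± 0.3). In the edgeR quasi-likelihood test, 6428 of 14995 genes were called, 3280 higher and 3148 lower, and 2173 of these changed at least 2-fold (1269 higher, 904 lower). By position on GRCh38 in the GENCODE 29 annotation, TGM2 (ENSG00000198959.12) lies on chromosome 20 from 38127387 to 38166578, CD38 (ENSG00000004468.13) on chromosome 4 from 15778275 to 15853230, and ITGAM (ENSG00000169896.18) on chromosome 16 from 31259967 to 31332892. Ratios against a group without counts use a floor of 3 counts over the group, between 0.0725 and 0.0794 CPM, which covers counting error only.

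**Figure D1:**
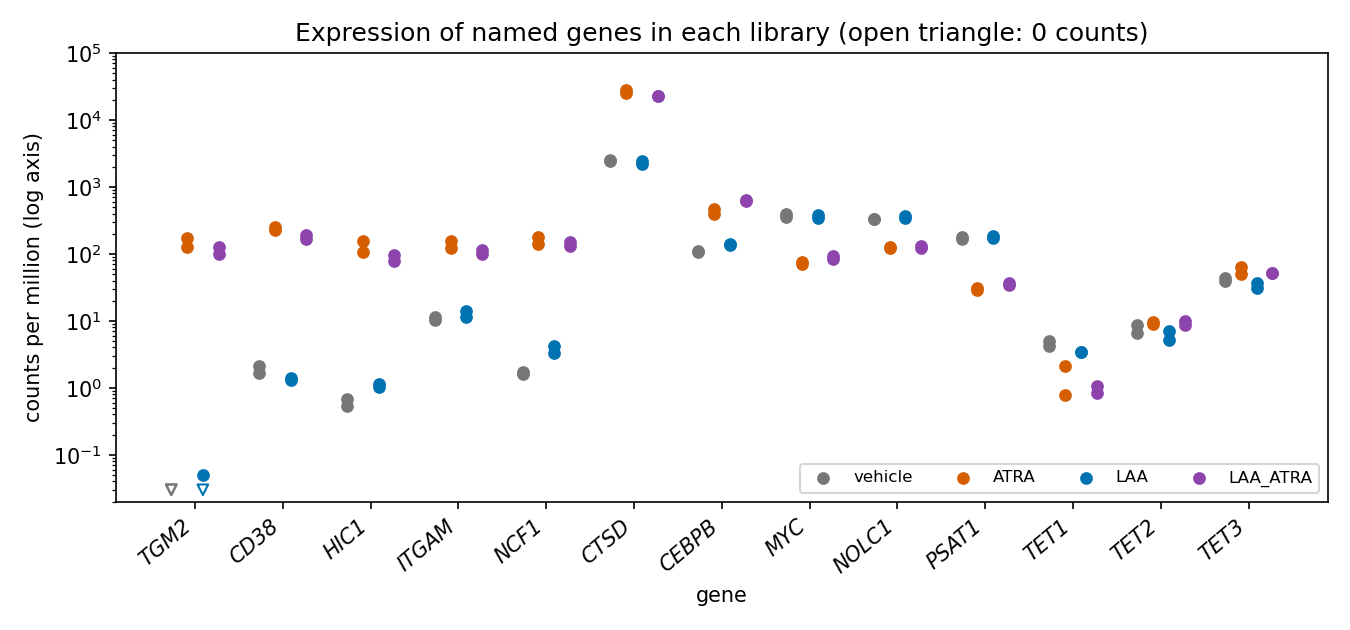
Normalised abundance per library (CPM, log axis) of genes named in the text in the 4 groups, with points for libraries and open triangles for libraries without counts. CD38 lies near 1.91 CPM in vehicle and near 240 CPM with ATRA, and TGM2 has no counts in either vehicle library.

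Most lists of myeloid genes rose with ATRA. Of 17 retinoid-response genes tested, 11 rose and 2 fell (12 and 2 adjusted over the list alone), among them DHRS3, a retinal reductase, at 16.2-fold (camera adjusted p = 4.65e-05, and adjusted p = 0.219 with an estimated correlation). CYP26A1, the retinoic acid hydroxylase, had 4 counts over all libraries and was not tested. Of 16 monocyte and macrophage markers, 10 rose and 4 fell, the same numbers adjusted over the list alone (adjusted p = 0.00237, and adjusted p = 0.167 with an estimated correlation). The cathepsin CTSD reached 26400 CPM from 2490, and the scavenger receptor CD68 rose 7.51-fold, whereas the galectin LGALS3 fell (log2 fold change -2.13 ± 0.17). Other textbook markers were near 0 in every library, with 18 counts in all for CD14 and 15 for CD163. Of 10 neutrophil and granulocyte markers, 9 rose, among them the calgranulin S100A9 (15.9-fold) and the G-CSF receptor CSF3R (3.52-fold), and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 2.81e-05, and adjusted p = 0.144 with an estimated correlation). That list holds 22 genes, and the rest were too low to test, such as LTF with 14 counts in all, MMP8 with 16 and LCN2 with 2. Of 8 NADPH oxidase genes, 6 rose and none fell (6 and 1 adjusted over the list alone, adjusted p = 3.95e-05, and adjusted p = 0.0826 with an estimated correlation). CYBB, the catalytic subunit, rose 35.9-fold and NCF1, a cytosolic subunit with near-identical pseudogenes, 96.2-fold. Of 18 myeloid transcription factors, 10 rose, such as CEBPE (4.82-fold), CEBPB (3.91-fold) and ID1 (14.3-fold), and 3 fell (11 and 4 adjusted over the list alone, adjusted p = 0.00228, and adjusted p = 0.086 with an estimated correlation). Of 20 progenitor and primary granule genes, 8 rose and 6 fell, also adjusted over the list alone, without a call (adjusted p = 0.274). Within that list the primary granule proteases PRTN3 (4.01-fold) and ELANE (2.18-fold) rose while the proto-oncogene MYC fell (log2 fold change -2.37 ± 0.11, adjusted p = 1.11e-08).

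Adhesion receptors, interferon-stimulated genes and lipid efflux genes were also called higher with ATRA. Of 23 adhesion and migration receptors, 18 rose and 2 fell (19 and 2 adjusted over the list alone), with the chemokine receptor CCR1 at 8.69-fold and the integrin chain ITGB2 at 2.89-fold (adjusted p = 3e-07, and adjusted p = 0.0826 with an estimated correlation). Of 31 interferon-stimulated genes, 16 rose and 4 fell, also adjusted over the list alone, with the transcription factor IRF1 at 9.07-fold and the antiviral synthetase OAS1 at 13.9-fold (adjusted p = 0.000178, and adjusted p = 0.0826 with an estimated correlation). Of 15 lipid efflux and LXR target genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone), with the scavenger receptor CD36 at 20.3-fold, the oxysterol receptor NR1H3 at 8.84-fold and the phospholipid transfer protein PLTP at 5.75-fold (adjusted p = 2.81e-05, and adjusted p = 0.086 with an estimated correlation). Of 18 antigen-presentation genes, 10 rose and 1 fell, also adjusted over the list alone, with the cathepsin CTSS at 2.57-fold. Their call (adjusted p = 0.0166, and adjusted p = 0.442 with an estimated correlation) was lost after a correction for transcript length and GC content (adjusted p = 0.0692). Of 26 apoptosis regulators, 13 rose and 4 fell, also adjusted over the list alone, with the death effector BAX up 1.88-fold and the survival factor BCL2 down (log2 fold change -1.73 ± 0.16). This list was called (adjusted p = 0.0283, and adjusted p = 0.442 with an estimated correlation) but not without ATRA replicate 2 (adjusted p = 0.05). Its median log2 fold change was 0.31 and its mean -0.01.

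MYC targets and DNA replication genes were called lower with ATRA. Of 29 MYC targets and ribosome biogenesis genes, none rose and 26 fell, also adjusted over the list alone, with a median log2 fold change of -0.78. Examples were the nucleolar factor NOLC1 (-1.43 ± 0.095) and spermidine synthase, SRM (-1.26 ± 0.11), and camera gave adjusted p = 4.46e-12, and adjusted p = 0.086 with an estimated correlation. Of 30 DNA replication genes, 21 fell and 3 rose, also adjusted over the list alone (adjusted p = 2.81e-05, and adjusted p = 0.0826 with an estimated correlation). The licensing factor CDT1 fell (-1.29 ± 0.14), as did the helicase subunit MCM6 (-0.81 ± 0.091), and the origin subunit ORC6 rose (1.15 ± 0.11). The cell cycle inhibitor CDKN1A rose 6.56-fold and the cyclin CCND2 fell (-1.56 ± 0.15), in a list of 18 inhibitors and G1 genes with 7 up and 2 down (8 and 3 adjusted over the list alone, adjusted p = 0.168). Of 25 G2 and mitosis genes, 2 rose and 7 fell (adjusted p = 0.065). Hypoxia and HIF targets were called lower, with 9 of 21 down and 3 up, such as the kinase PDK1 (-1.36 ± 0.14) (adjusted p = 0.0376, and adjusted p = 0.777 with an estimated correlation). That call was lost without vehicle replicate 2, ATRA replicate 2, LAA replicate 1 or LAA replicate 2 (adjusted p up to 0.226) and after the length and GC correction (adjusted p = 0.0692).

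The remaining lists were not called with ATRA, although some had members that moved far in both directions. In glycolysis the hexokinase HK3 rose 61.2-fold while its relative HK2 fell (-1.91 ± 0.18), with 4 of 22 genes up and 9 down (4 and 10 adjusted over the list alone, adjusted p = 0.274). Among 22 unfolded-protein and amino acid stress genes, 3 rose and 8 fell (adjusted p = 0.0796), and the serine synthesis enzymes PSAT1 (-2.53 ± 0.11) and PHGDH (-1.9 ± 0.1) were among the falls. Of 21 NRF2 antioxidant targets, 7 rose and 6 fell (adjusted p = 0.424), from the pentose phosphate enzyme PGD (4.5-fold) to the peroxiredoxin PRDX1 (-1.64 ± 0.13). Cholesterol synthesis had 1 of 21 up and 9 down (adjusted p = 0.065), oxidative phosphorylation 2 of 25 up and 9 down (adjusted p = 0.0941), iron handling 3 of 14 up and 6 down (adjusted p = 0.575), and ascorbate transport and recycling 3 of 12 up and 2 down (adjusted p = 0.734). Cytokines and chemokines had 3 of 14 up and 3 down (adjusted p = 0.671), TET and DNA methylation enzymes 4 of 17 up and 6 down (adjusted p = 0.671), and markers of other lineages 2 of 12 up and 1 down (adjusted p = 0.916). Mitochondrially encoded transcripts had 3 of 13 up and none down (adjusted p = 0.195). Without ATRA replicate 2 the G2 and mitosis (0.0151), cholesterol (0.0348), stress (0.0174), oxidative phosphorylation (0.00293) and mitochondrial lists (0.0174) were called, as were the cholesterol and stress lists without vehicle replicate 1. With the length and GC correction the cholesterol list was called too (adjusted p = 0.0153). The median and the mean differed in sign for glycolysis (-0.19 and 0.02), iron handling (-0.27 and 0.06), cytokines (-0.12 and 0.06) and other lineages (0.08 and -0.18), and the test took the sign of the median in each.

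**Figure D2:**
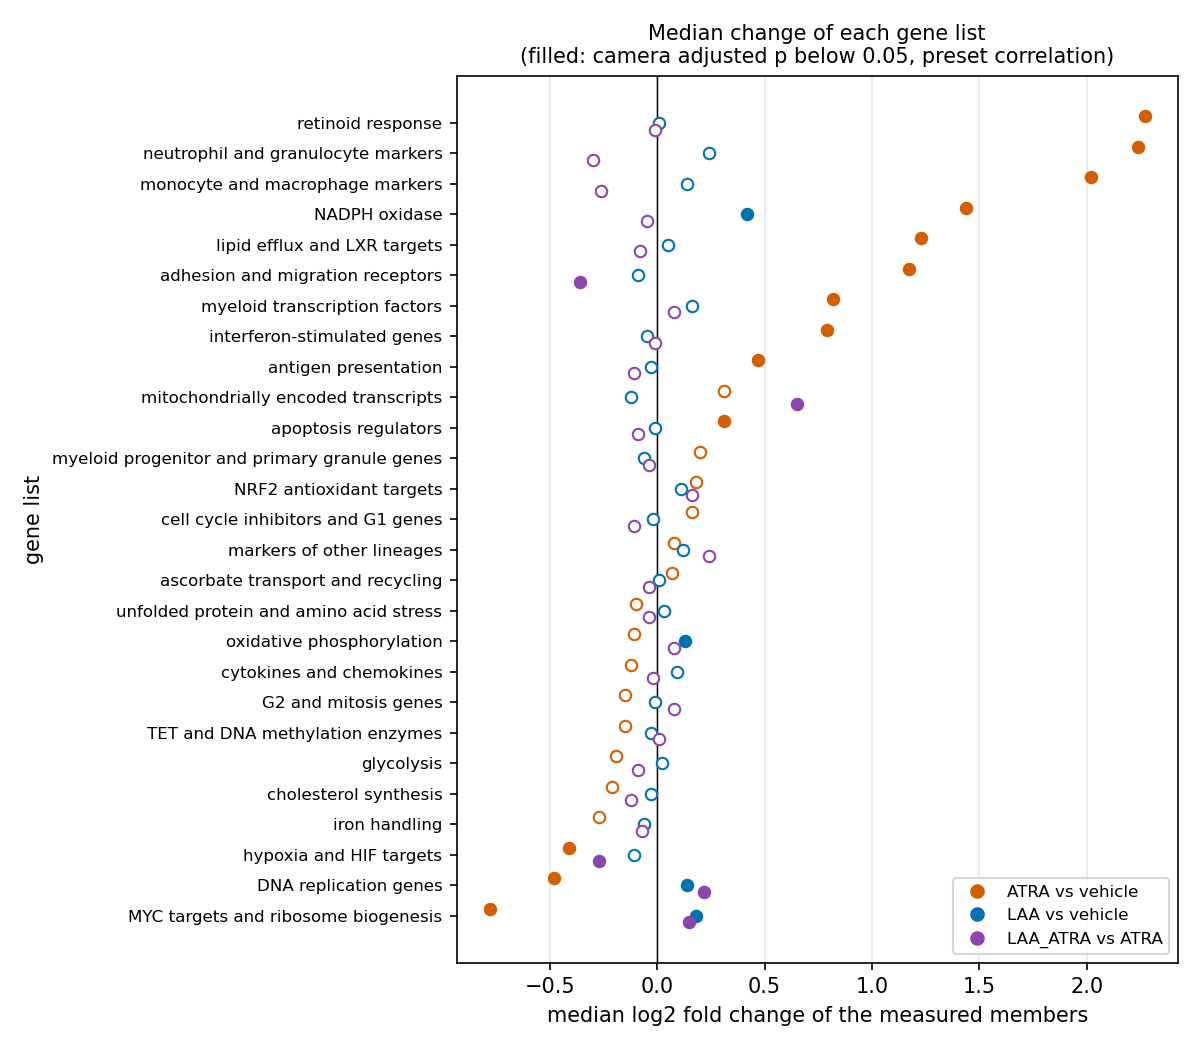
Median log2 fold change of each gene list (horizontal axis) in the comparisons, with genes lacking counts in 1 group placed at their bound. With ATRA the MYC and ribosome biogenesis list has a median of -0.78, and with LAA alone 0.18.

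None of the genes the series is about was called for LAA against vehicle. TET2, the methylcytosine dioxygenase named in the series title, had 7.68 ± 1.39 CPM in vehicle, 6.05 ± 1.34 with LAA, 9.33 ± 0.497 with ATRA and 9.37 ± 0.833 with both. Its log2 fold change was -0.34 ± 0.21 with LAA (adjusted p = 0.41), 0.28 ± 0.2 with ATRA (adjusted p = 0.294) and 0.01 ± 0.2 for LAA+ATRA against ATRA (adjusted p = 0.991). It was called only for LAA+ATRA against LAA (0.63 ± 0.21, adjusted p = 0.0318), and not without LAA replicate 2 (0.42, adjusted p = 0.241) or LAA+ATRA replicate 2 (0.54, adjusted p = 0.141), nor with DESeq2 or on FPKM. With the length and GC correction it was also called for LAA+ATRA against vehicle (adjusted p = 0.02). Its relative TET1 fell with ATRA from 4.61 ± 0.624 to 1.44 ± 0.937 CPM (-1.71 ± 0.41, adjusted p = 0.00499), by -2.55 without ATRA replicate 1 and -1.13 without ATRA replicate 2. TET3 rose with ATRA (0.43 ± 0.13, adjusted p = 0.0171), but was not called without vehicle replicate 2 (0.35, adjusted p = 0.146) or ATRA replicate 1 (0.27, adjusted p = 0.133), nor on FPKM. The retinoic acid receptor RARA was not called with ATRA (0.14 ± 0.14, adjusted p = 0.466), and its relative RARB, itself a retinoid target, rose from 0.774 ± 0.209 to 6.85 ± 1.24 CPM (adjusted p = 1.49e-05). With LAA alone RARB had a log2 fold change of -2.29 ± 0.54 at few counts (adjusted p = 0.0612), called without ATRA replicate 1 (adjusted p = 0.0447) and without the low-count filter. The ascorbate transporter SLC23A2 fell with ATRA (-0.44 ± 0.098, adjusted p = 0.00308) and was not called with LAA (-0.32 ± 0.098, adjusted p = 0.118) except in the fit to only the libraries compared (0.0137).

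LAA alone gave small changes, and few genes passed the adjusted threshold in the fit to all libraries. That fit uses the same spread per gene for all groups, although replicates differed unequally. Their median absolute log2 difference was 0.0871 in vehicle, 0.101 with LAA, 0.16 with ATRA and 0.155 with LAA+ATRA. The numbers called with and without ATRA therefore do not show where LAA had the larger effect. EXOSC4, an RNA exosome subunit, rose from 28.9 ± 1.04 to 50.4 ± 2.1 CPM (log2 fold change 0.8 ± 0.11, adjusted p = 0.0326). ERMP1, an endoplasmic reticulum peptidase, fell from 56 ± 0.852 to 33.9 ± 1.09 CPM (-0.72 ± 0.098, adjusted p = 0.0326). EXOSC4 was not called without vehicle replicate 1 (adjusted p = 0.407), vehicle replicate 2 (0.17), LAA replicate 1 (0.109) or LAA replicate 2 (0.296), and for ERMP1 the values were 0.407, 0.129, 0.159 and 0.296. Both lost the call with the replicate number as a block and on FPKM. The other called genes, ENSG00000230955.1 and ENSG00000266642.2, fell outside the rule for named genes because they have no symbol and were singled out after their values were seen. They had no counts in vehicle and 1.94 and 3.09 CPM with LAA. In all, 4 of 14995 genes were called, 3 higher and 1 lower, and 2833 (18.9%) had an unadjusted p under 0.05. The number called was 0 without vehicle replicate 1, vehicle replicate 2 or LAA replicate 1, 2 without LAA replicate 2, 469 without ATRA replicate 1, 429 without ATRA replicate 2, 287 without LAA+ATRA replicate 1 and 345 without LAA+ATRA replicate 2. DESeq2 called 663 genes and edgeR without the low-count filter 828, whereas a fit to the vehicle and LAA libraries alone called 2187. The differentiation genes CD38 (-0.49 ± 0.24, adjusted p = 0.289) and ITGAM (0.24 ± 0.16, adjusted p = 0.465) were not called. CSF3R had a log2 fold change of -0.43 ± 0.11 (adjusted p = 0.0871), called without ATRA replicate 1 (0.0339) or ATRA replicate 2 (0.0393), with DESeq2, without the low-count filter and with only the libraries compared.

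By list, 4 of 27 were called as higher with LAA alone, although none of their members was called over all genes. Of 29 MYC targets and ribosome biogenesis genes none was called singly, but 9 rose adjusted over the list alone, and the median log2 fold change was 0.18 (adjusted p = 1.26e-06, and adjusted p = 0.385 with an estimated correlation). DNA replication genes had a median of 0.14 with no gene called either way (adjusted p = 0.00684, and adjusted p = 0.385 with an estimated correlation). Of 8 NADPH oxidase genes, 4 rose adjusted over the list alone, with a median of 0.42 (adjusted p = 0.0245, and adjusted p = 0.385 with an estimated correlation). The membrane subunit CYBA went from 199 ± 3.48 to 276 ± 16.7 CPM (0.47 ± 0.14, adjusted p = 0.109), and was called without LAA+ATRA replicate 1 (0.0426) or LAA+ATRA replicate 2 (0.0382), with DESeq2, without the low-count filter and with only the libraries compared. Oxidative phosphorylation genes had a median of 0.13, with 3 of 25 up adjusted over the list alone (adjusted p = 0.0132, and adjusted p = 0.985 with an estimated correlation), and were not called without LAA replicate 1 (adjusted p = 0.056). With the length and GC correction neither the NADPH oxidase list (adjusted p = 0.143) nor oxidative phosphorylation (adjusted p = 0.249) was called, whereas the progenitor and primary granule list was called as lower (adjusted p = 0.0112, from 0.716). The NRF2 targets (median 0.11, adjusted p = 0.107), hypoxia and HIF targets (median -0.11, adjusted p = 0.0969), the TET and DNA methylation enzymes (median -0.03, adjusted p = 0.947) and ascorbate transport genes (median 0.01, adjusted p = 0.947) were not called. The hypoxia list was called without vehicle replicate 1 or LAA+ATRA replicate 1, with adjusted p from 0.00017 to 0.874 over the 8 fits that left out 1 library.

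In cells given ATRA, LAA changed a limited set of genes. LBP, the lipopolysaccharide-binding protein, rose from 3.14 ± 0.0679 CPM with ATRA to 15.8 ± 1.66 CPM with LAA+ATRA (log2 fold change 2.32 ± 0.23, adjusted p = 0.00252). GAL, a neuropeptide precursor that ATRA alone lowered from 54.1 ± 2.79 to 3.9 ± 0.896 CPM, stood at 9.43 ± 0.529 CPM with both compounds (1.26 ± 0.16, adjusted p = 0.0179). The complement receptor CR1 fell from 57.7 ± 4.35 to 30.1 ± 2.71 CPM (-0.94 ± 0.12, adjusted p = 0.0179) and TAPBPL, a peptide-loading factor, from 39.2 ± 0.57 to 20.1 ± 0.536 CPM (-0.96 ± 0.13, adjusted p = 0.0194). LBP, GAL, CR1 and TAPBPL were called in all 8 fits that left out 1 library, but not in every alternative. LBP lost the call on log2(FPKM + 0.1) (adjusted p = 0.0944), and CR1 (up to 0.232) and TAPBPL (up to 0.123) on FPKM at both pseudocounts. GAL lost it on FPKM at both pseudocounts and with only the libraries compared (up to 0.0944). CCR1 fell from 62 ± 1.4 to 38 ± 1.91 CPM (-0.71 ± 0.11, adjusted p = 0.0203), and was not called without LAA replicate 1 (0.0537), LAA replicate 2 (0.0538), LAA+ATRA replicate 1 (0.0522) or LAA+ATRA replicate 2 (0.0517), nor with only the libraries compared or on FPKM (up to 0.0944). CEBPB rose further (0.55 ± 0.1, adjusted p = 0.0402), but lost the call without any 1 library other than ATRA replicate 1 (adjusted p from 0.0551 to 0.0891). It also lost the call with the replicate number as a block, with only the libraries compared (0.192), on FPKM (up to 0.0944) and with the length and GC correction, where the log2 fold change was 0.33 ± 0.076. ITGB2 fell (-0.58 ± 0.12, adjusted p = 0.0491), and only the fits without ATRA replicate 2 or LAA+ATRA replicate 1 kept the call, with adjusted p up to 0.101 in the others. The transcription factor BATF3 (0.85 ± 0.16, adjusted p = 0.0388) and the growth factor HBEGF (-0.9 ± 0.19, adjusted p = 0.0486) lost the call whichever library was left out. ITGB2 (adjusted p up to 0.207), BATF3 (up to 0.191) and HBEGF (up to 0.159) also lost it with the replicate number as a block, with only the libraries compared and on FPKM. FAM156B, which has a near-identical copy, rose 5.4-fold (log2 fold change 2.43, from 1.65 to 3.84 without 1 library, adjusted p = 0.0245) and was not called without LAA replicate 1 (0.0537), LAA replicate 2 (0.0538), LAA+ATRA replicate 1 (0.0545) or LAA+ATRA replicate 2 (0.0541), nor with only the libraries compared or on FPKM (up to 0.0951). The antisense transcript TUBA1B-AS1, at 199 ± 206 CPM with both compounds, rested on single libraries (log2 fold change 4.88, from 2.98 to 5.67 without 1 library) and lost the call without ATRA replicate 1 (0.0885), ATRA replicate 2 (0.0844), LAA replicate 1 (0.0537), LAA replicate 2 (0.0538) or LAA+ATRA replicate 2 (0.0869), and with the block or on FPKM (up to 0.0944).

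CD38 and ITGAM were not raised further by adding LAA to ATRA. CD38 had a log2 fold change of -0.41 ± 0.11 (adjusted p = 0.0808), called as lower with DESeq2 and without the low-count filter (adjusted p down to 0.0155), and ITGAM had -0.36 ± 0.13 (adjusted p = 0.166). In all, 152 genes were called, 74 higher and 78 lower, of which 18 changed at least 2-fold, 16 up and 2 down. An unadjusted p under 0.05 was seen for 2782 genes (18.6%). The number called was 27 without vehicle replicate 1, 28 without vehicle replicate 2, 6 without LAA replicate 1, 6 without LAA replicate 2 and 47 without LAA+ATRA replicate 1. A fit to the ATRA and LAA+ATRA libraries alone called 15 genes, a fit with the replicate number as a block 30 and limma on FPKM 6, whereas DESeq2 called 648 and edgeR without the low-count filter 903. Of the 27 lists, 5 were called, and 9 without ATRA replicate 2 or 14 without LAA+ATRA replicate 1. Of 23 adhesion and migration receptors, 3 fell (1 up and 11 down adjusted over the list alone), with a median log2 fold change of -0.36 (adjusted p = 7.58e-09, and adjusted p = 0.0898 with an estimated correlation). DNA replication genes had a median of 0.22 and 9 of 30 up adjusted over the list alone (adjusted p = 1.71e-07, and adjusted p = 0.0833 with an estimated correlation). MYC targets and ribosome biogenesis genes had a median of 0.15 and 6 of 29 up adjusted over the list alone (adjusted p = 8.06e-05, and adjusted p = 0.532 with an estimated correlation). Hypoxia and HIF targets had a median of -0.27 (adjusted p = 8.41e-05, and adjusted p = 0.638 with an estimated correlation), lost without ATRA replicate 1 or LAA+ATRA replicate 2 (adjusted p up to 0.765). The retinoid response list was not called (median -0.01, adjusted p = 0.342) except without LAA+ATRA replicate 1 (0.0326) and with the length and GC correction (0.0378), both lower.

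For LAA+ATRA against ATRA, the other lists of differentiation genes were not called. Monocyte and macrophage markers had a median log2 fold change of -0.25 (adjusted p = 0.088), neutrophil and granulocyte markers -0.3 (0.212), antigen presentation -0.11 (0.212) and lipid efflux and LXR targets -0.08 (0.106). Myeloid transcription factors had a median of 0.08 (adjusted p = 0.356), and NADPH oxidase genes -0.05 with the test pointing up (0.968). With the length and GC correction, the monocyte (0.0113), neutrophil (0.0115), antigen presentation (0.0206) and lipid efflux (0.0252) lists were called as lower. So were cholesterol synthesis (0.0252), glycolysis (0.0115) and the cell cycle inhibitors (0.0378), and the G2 and mitosis genes were called as higher (0.00434). Leaving out LAA+ATRA replicate 1 gave calls as lower for antigen presentation (0.00815), lipid efflux (0.0112), cholesterol synthesis (0.000377), the cell cycle inhibitors (0.0326) and the apoptosis regulators (0.0326), and a call as higher for the NRF2 targets (0.0112). The monocyte markers (down to 0.0129) and glycolysis (down to 3.34e-06) were called without ATRA replicate 2 or LAA+ATRA replicate 1, G2 and mitosis (0.0177) and oxidative phosphorylation (0.0012) as higher without ATRA replicate 2, and the neutrophil markers in no such fit (0.0517 to 0.693).

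Mitochondrially encoded transcripts were higher with LAA+ATRA than with ATRA. The complex I gene MT-ND6 rose from 432 ± 37.6 to 719 ± 12.2 CPM (log2 fold change 0.73 ± 0.097, adjusted p = 0.0179), and was not called without LAA replicate 1 (0.0537) or LAA replicate 2 (0.0538). It also lost the call with only the libraries compared and on FPKM (up to 0.0944), and with the length and GC correction, where its log2 fold change shrank to 0.28 ± 0.074. Of 13 such transcripts, 6 were called and all 6 rose (12 up adjusted over the list alone), with a median of 0.65 (adjusted p = 1.8e-12, and adjusted p = 0.532 with an estimated correlation). The estimated correlation between these transcripts was 0.719, and 0.718 in the interaction, against the preset 0.01. The 13 transcripts are therefore far from independent evidence, and the adjusted p at the preset correlation overstates it. With the length and GC correction the list remained past the threshold (adjusted p = 0.00263). With LAA alone against vehicle the list had a median of -0.12 (adjusted p = 0.174), called as lower without LAA replicate 1 (0.0345) or LAA+ATRA replicate 1 and with the length and GC correction (3.69e-06). The share of these transcripts in all counts was 3.38% ± 0.11 in vehicle, 3.56% ± 0.35 with ATRA, 2.9% ± 0.24 with LAA and 4.94% ± 1.1 with both (SD, n = 2). The LAA+ATRA libraries held 4.16% and 5.72%, against 3.81% and 3.31% for ATRA.

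The libraries also differed in how counts depended on transcript length. The slope of relative abundance on log2 transcript length, over 10705 genes, was 0.122 and 0.0842 in vehicle, 0.0646 and 0.00164 with ATRA, -0.0449 and -0.0349 with LAA, and -0.124 and -0.0686 with LAA+ATRA. All 4 libraries with LAA lay below all 4 without it (two-sided exact permutation p = 0.0286 over 70 splits), and p was 0.0556 over the 36 exchanges that kept the ATRA treatment fixed. These are the smallest p-values that so few splits can give, so the second could not have passed 0.05. Length and GC content together accounted for 28.3% of the variance of log2 fold changes across genes for LAA against vehicle, 18.3% for LAA+ATRA against ATRA and 2.16% for ATRA against vehicle. The trend coincides with the LAA treatment, so the design alone does not separate them. Lists of short or long transcripts in the LAA comparisons carry that limit.

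**Figure D3:**
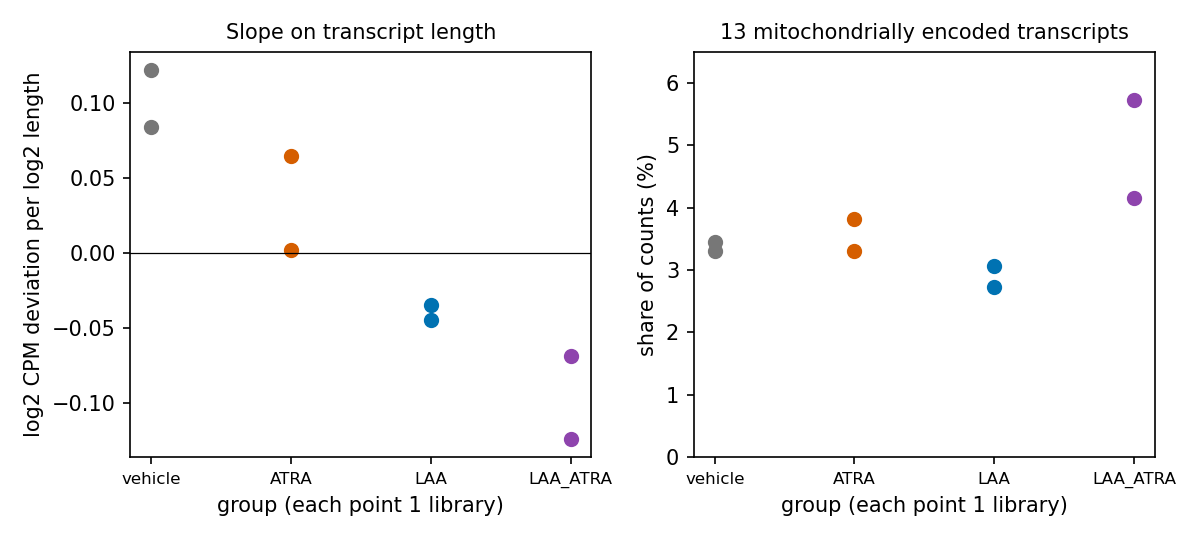
Slope of relative abundance on log2 transcript length and share of mitochondrially encoded counts (percent) for each library, as points by group. Slopes fall from 0.122 in a vehicle library to -0.124 in an LAA+ATRA library, and the highest mitochondrial share is 5.72%.

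The LAA effect pointed the same way with and without ATRA for most genes that moved. Of the 152 genes called for LAA+ATRA against ATRA, 139 (91.4%) had the same sign for LAA against vehicle. Across all 14995 genes, which are not independent replicates, the log2 fold changes of LAA against vehicle and of LAA+ATRA against ATRA had Pearson's r of 0.177 and Spearman's rho of 0.394, and at a mean of at least 10 CPM 0.524 and 0.656. That Pearson's r was 0.37 with the length and GC correction, which removes a trend that both LAA comparisons share. Of the genes at unadjusted p under 0.05 for LAA against vehicle, 88.4% had the same sign for LAA+ATRA against ATRA, and 81.5% of those at that threshold with the correction. Only 1 gene was called in both, in the same direction. The ATRA effect with and without LAA had Pearson's r of 0.733 and Spearman's rho of 0.8 across genes, and 2398 genes were called higher in both and 2296 lower in both (602 and 566 if independent). In the opposite direction there was 1.

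**Figure D4:**
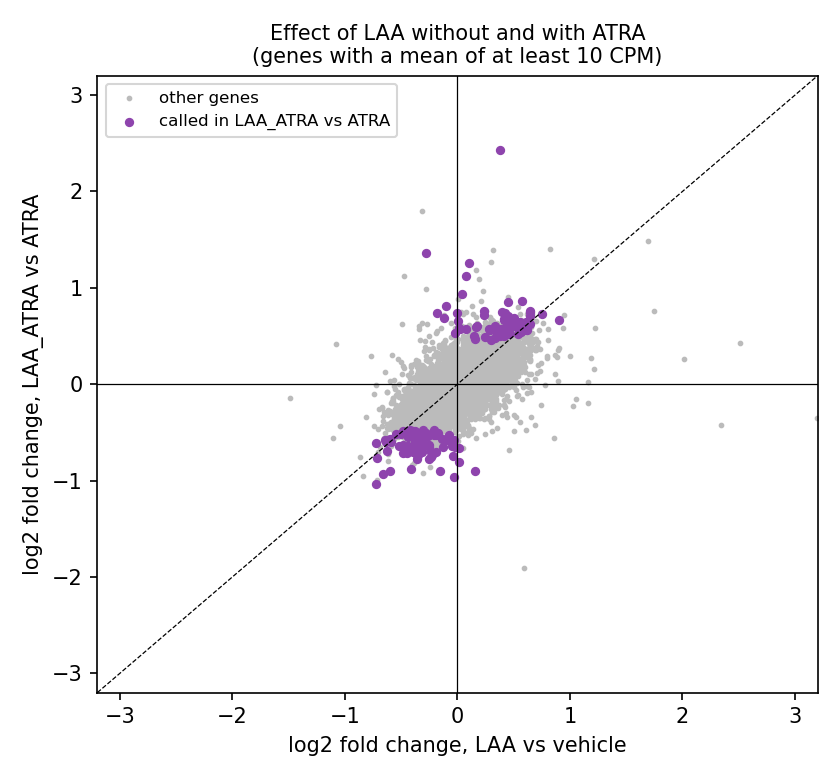
Log2 fold change of each gene for LAA against vehicle (horizontal axis) and for LAA+ATRA against ATRA (vertical axis), at a mean of at least 10 CPM. Of the 139 genes at that level called for LAA+ATRA against ATRA, some of them beyond the axes, 128 (92.1%) have the same sign in both comparisons.

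Against vehicle, the combination raised CD38 and ITGAM and lowered MYC. CD38 rose from 1.91 ± 0.318 to 181 ± 16.3 CPM (log2 fold change 6.56 ± 0.16, adjusted p = 2.14e-10) and ITGAM from 10.8 ± 0.948 to 107 ± 11.3 CPM (3.3 ± 0.15, adjusted p = 1.56e-08). TGM2 was at least 1540-fold higher, and MYC fell (-2.09 ± 0.11). The bone morphogenetic protein antagonist NOG (-4.14 ± 0.22) and the matricellular protein CCN3 (-3.78 ± 0.18) were among the largest falls, with PDYN (-4.16 ± 0.3). MT-ND6 rose 2.36-fold. TET1 fell (-2.27 ± 0.43, adjusted p = 0.00104), RARB rose 6.37-fold and SLC23A2 fell (-0.56 ± 0.098), while TET2 (0.29 ± 0.2, adjusted p = 0.275) and RARA (0.18 ± 0.14, adjusted p = 0.333) were not called. TET3 had 0.32 ± 0.13 (adjusted p = 0.0643), and was called without ATRA replicate 1 (0.0297) or ATRA replicate 2 (0.0339), without the low-count filter, with only the libraries compared and with the length and GC correction (adjusted p down to 0.00118). In all, 6701 genes were called, 3471 higher and 3230 lower, and 2205 changed at least 2-fold (1361 up, 844 down). Of 27 lists, 15 were called, 10 up and 5 down, with adjusted p from 0.165 to 0.594 with an estimated correlation. Retinoid response had 10 of 17 up and 2 down, interferon-stimulated genes 18 of 31 up and 4 down, adhesion receptors 15 of 23 up and 2 down, MYC targets 20 of 29 down and none up, and mitochondrially encoded transcripts 12 of 13 up and none down (adjusted p = 4.3e-05). Glycolysis (adjusted p = 0.0815) was called as lower with the length and GC correction (0.014) and without vehicle replicate 1 or LAA+ATRA replicate 1 (down to 0.00213). Antigen presentation (adjusted p = 0.0393) was not called without vehicle replicate 2 or LAA+ATRA replicate 1 (up to 0.0941) or with the length and GC correction (0.305), DNA replication (0.0261) not without vehicle replicate 2 (0.0514), and cholesterol synthesis (0.0114) not without LAA+ATRA replicate 2 (0.0698).

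Against LAA alone, the combination raised CD38 and ITGAM. CD38 rose from 1.35 ± 0.0906 to 181 ± 16.3 CPM (log2 fold change 7.06 ± 0.17, adjusted p = 1.91e-10) and ITGAM 8.36-fold (adjusted p = 2.8e-08). DAAM2, without counts with LAA, was at least 559-fold higher. NOG (-4.2 ± 0.22) and CCN3 (-3.59 ± 0.18) fell, TET1 fell (-1.85 ± 0.44, adjusted p = 0.0053), and TET3 (0.64 ± 0.13, adjusted p = 0.00245) and RARB (31.1-fold) rose, TET3 without a call on FPKM, whereas RARA (0.22 ± 0.14, adjusted p = 0.259) and SLC23A2 (-0.24 ± 0.099, adjusted p = 0.0724) were not called. RARB had few counts in LAA, 0.155 ± 0.0784 CPM, and its log2 fold change ran from 4.52 to 5.56 without 1 library. In all, 5451 genes were called, 2754 higher and 2697 lower, with 987 up and 681 down at least 2-fold. Of 27 lists, 17 were called, 10 up and 7 down, with adjusted p from 0.0667 to 0.608 with an estimated correlation. MYC targets and ribosome biogenesis genes had 28 of 29 down and oxidative phosphorylation 9 of 25 down, with none up in either, while mitochondrially encoded transcripts had 12 of 13 up and none down. Hypoxia targets (adjusted p = 0.00219) were not called without LAA+ATRA replicate 2 (0.189), antigen presentation (0.017) not without LAA+ATRA replicate 1 (0.0631) or with the length and GC correction (0.0624), and glycolysis (0.043) not without LAA replicate 2 or LAA+ATRA replicate 2 (up to 0.32).

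Whether the effect of the pair differed from the sum of the single effects was tested as an interaction. EIF3CL was the only gene of 14995 called (1 up, 0 down, adjusted p = 0.00106). It encodes a near-identical copy of the initiation factor subunit EIF3C, lies on chromosome 16 from 28379579 to 28403879, and had 28.4 ± 8.36 CPM in vehicle, 24.4 ± 12.7 with LAA, 34.3 ± 5.07 with both and no counts with ATRA. It was at least 391-fold lower with ATRA than in vehicle, and at least 471-fold higher with LAA+ATRA than with ATRA (adjusted p = 0.000233). With the counts of EIF3C and EIF3CL summed, the interaction was 0.07 ± 0.16 (adjusted p = 1), but a loss of EIF3CL would move that sum by only 0.11. CD38 (0.09 ± 0.26, adjusted p = 1), ITGAM (-0.6 ± 0.21, adjusted p = 0.856), ITGB2 (-0.48 ± 0.17, adjusted p = 0.874), TET2 (0.35 ± 0.29, adjusted p = 0.986), TET1 (-0.14 ± 0.6, adjusted p = 1), TET3 (0.2 ± 0.18, adjusted p = 0.99), RARA (0.08 ± 0.2, adjusted p = 1), RARB (1.82 ± 0.62, adjusted p = 0.843) and SLC23A2 (0.2 ± 0.14, adjusted p = 0.986) were not called. An unadjusted p under 0.05 was seen for 747 genes (4.98%). The number called was 15 without ATRA replicate 1 and 4 without ATRA replicate 2, and DESeq2 called 11, edgeR without the low-count filter 136 and limma on FPKM 2. With limma on log2(FPKM + 1) EIF3CL itself was not called (adjusted p = 0.122). In simulated counts at this depth, the interaction recovered 71.6% of genes changed 2-fold and 8.96% of those changed 1.5-fold. The changed genes had a mean of at least 5 CPM in vehicle. Departures of 1.5-fold were therefore rarely detected singly, and genes with fewer counts were not simulated as changed.

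By list, 8 of 27 were called in the interaction, 3 up and 5 down, 12 without LAA+ATRA replicate 1, and 2 without vehicle replicate 1, LAA replicate 2 or LAA+ATRA replicate 2. Mitochondrially encoded transcripts were higher with the pair than the sum of single effects (median log2 0.81, 12 of 13 up adjusted over the list alone, none over all genes, adjusted p = 4.76e-22, and adjusted p = 0.315 with an estimated correlation), among them the oxidase subunit MT-CO1 (0.79 ± 0.19, adjusted p = 0.662), which was called with DESeq2 and without the low-count filter (adjusted p down to 1.19e-05). Adhesion and migration receptors were lower (median -0.2, adjusted p = 0.000524, and adjusted p = 0.315 with an estimated correlation). Both held in every fit that left out 1 library. Neutrophil markers (median -0.74, 3 of 10 down adjusted over the list alone, adjusted p = 0.0178, and adjusted p = 0.456 with an estimated correlation) and NADPH oxidase genes (median -0.26, 3 of 8 down adjusted over the list alone, adjusted p = 0.0262, and adjusted p = 0.315 with an estimated correlation) were lower, and were lost without vehicle replicate 1, LAA replicate 2 or LAA+ATRA replicate 2 (up to 0.14 and 0.127). Lipid efflux and LXR targets were lower (median -0.3, adjusted p = 0.0178, and adjusted p = 0.369 with an estimated correlation), lost without any of those or ATRA replicate 2 (up to 0.182). Glycolysis was lower (median -0.09, adjusted p = 0.0356, and adjusted p = 0.723 with an estimated correlation), lost without vehicle replicate 1, ATRA replicate 1, LAA replicate 2 or LAA+ATRA replicate 2 (up to 0.933) and with the length and GC correction (0.118). G2 and mitosis genes (median 0.08, adjusted p = 0.0356, and adjusted p = 0.369 with an estimated correlation) held only without vehicle replicate 2 or ATRA replicate 2, and DNA replication genes (median 0.06, adjusted p = 0.0413, and adjusted p = 0.315 with an estimated correlation) only without ATRA replicate 2, with adjusted p up to 0.252 and 0.14 in the other fits. The retinoid response list was not called (median -0.02, adjusted p = 0.771). Lists not called in the fit to all libraries but called as lower in some fit without 1 library were hypoxia targets (down to 1.04e-08), cholesterol synthesis (0.000577), oxidative phosphorylation (0.000953), apoptosis regulators (0.0249), antigen presentation (0.0249), monocyte markers (0.0467) and the stress genes (0.0471).

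Comparisons that use the same vehicle libraries share their noise. For ATRA and LAA+ATRA against vehicle, 5118 genes were called in the same direction, against 1437 if the calls were independent, and 2 in opposite directions. Over 20 simulations with no treatment effect the mean was 0.25. Those simulations leave few genes to call and lack the ATRA effect that both comparisons share, so they cannot show how much shared noise adds to the overlap. Pearson's r across genes was 0.843, and 0.499 on average in the simulations. For LAA and LAA+ATRA against vehicle there were 4 (0.9098 if independent, and 0.2 on average in the simulations), and for ATRA and LAA against vehicle 3 (0.8662 and 0.2). Pearson's r for these pairs was 0.448 and 0.344, against 0.487 and 0.499 in the simulations. With 2 vehicle libraries the vehicle group was not split between the comparisons.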

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

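The tests of library size, of a smaller ATRA response, of the shift that a loss of EIF3CL would give and of genes selected without 1 ATRA library were chosen after the results they concern had been seen. Those on transcript length and on summed copies of a gene were also chosen after the data had been examined. By a test of the interaction, the effect of LAA differed between cells with and without ATRA for EIF3CL (adjusted p = 0.00106) and, by camera, for the mitochondrially encoded transcripts (4.76e-22), the adhesion and migration receptors (0.000524), the neutrophil and granulocyte markers (0.0178), the lipid efflux and LXR targets (0.0178), the NADPH oxidase genes (0.0262), the G2 and mitosis genes (0.0356), glycolysis (0.0356) and the DNA replication genes (0.0413). With an estimated correlation none of the 8 lists was called (adjusted p from 0.315 to 0.723), and fry called 0. Within single lists no gene was called in the interaction over all genes.

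EIF3CL had no counts in either ATRA library, and between 15.4 and 37.9 CPM in the other 6. Its near-identical copy EIF3C had from 268 to 495 CPM in the 8 libraries. When the counts of both copies were summed, the interaction log2 fold change was 0.07 ± 0.16 (adjusted p = 1), while the sum fell with ATRA against vehicle (-0.73 ± 0.11, adjusted p = 0.000239). A loss of EIF3CL, which made up 7.3% of the sum on average in the other libraries, would move that interaction by only 0.11, within its standard error. Reads shared with EIF3C and a change specific to EIF3CL therefore cannot be told apart, since the sum is too imprecise for so small a part.

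LAA was followed by many small changes. With LAA against vehicle, 2833 genes (18.9%) had an unadjusted p under 0.05, and 88.4% of them had the same sign for LAA+ATRA against ATRA. Removing per-library trends on transcript length and GC content gave 2544 genes at that threshold, 81.5% of them with the same sign in both comparisons. These trends accounted for 28.3% of the variance of the fold changes. The correction also raised the number called for ATRA against vehicle from 6428 to 7171, so it did not act on the LAA effect alone. Its lengths came from a reference that may differ from the authors' annotation, so the removal may be incomplete. The 2544 genes therefore cannot show whether these trends are the whole cause. The lowest number over the 8 fits that left out 1 library was 1377, which argues against 1 deviating library, and 3 of the 4 libraries without LAA had totals within the range of the LAA libraries, which argues against library size. A response to LAA may explain these changes, but the length and GC trends and library size were not excluded. A preparation batch shared by the LAA libraries was not tested, and the length trend itself coincides with the treatment.

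Genes that ATRA raised tended to be lower with LAA+ATRA than with ATRA alone, with a median log2 fold change of -0.075 over the 3280 raised (61.4% below 0) and 0.069 over the 3148 lowered (61.3% above 0). With the length and GC correction the medians were -0.1 for raised and 0.096 for lowered genes, so the correction did not shrink them. The median of raised genes lay below the lowest of 100 matched random sets (-0.007). Those sets were not selected on the ATRA libraries, and selection alone gave a mean median of -0.032 in simulations with no LAA effect. The matched sets therefore cannot separate the trends from selection. Simulations with no LAA effect gave a lowest median of -0.04 over 40 runs, but they let each gene vary on its own, and when genes were selected without 1 ATRA library the medians against that library ran from -0.078 to -0.016 for raised genes and from 0 to 0.033 for lowered genes. The slope of LAA+ATRA against LAA on ATRA against vehicle over 939 genes was 0.826, from 0.74 to 0.841 without 1 library and from 0.945 to 0.997 in the simulations, but it restates the pattern. Selection on the shared ATRA libraries, a smaller ATRA response and the spread between replicates therefore cannot be told apart with 2 libraries per group.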

How the results depend on the processing

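The length and GC correction was chosen after the results were seen, and the other alternatives were planned. Counts of genes called were compared under every alternative but limma on log2(FPKM + 0.1). Those for ATRA against vehicle, LAA+ATRA against vehicle and LAA+ATRA against LAA stayed within 1.5 times the reported numbers. For LAA against vehicle (4 reported) the count was 663 with DESeq2, 828 without the low-count filter, 2 with the replicate block, 2187 with only the libraries compared, 2 with limma on log2(FPKM + 1), 21 with the length and GC correction and 0 to 469 without 1 library. For LAA+ATRA against ATRA (152) it was 648, 903, 30, 15, 6, 248 and 6 to 172 in the same order. For the interaction (1) it was 11 with DESeq2, 136 without the filter, 2 on FPKM and 1 to 15 without 1 library. The cause was not tested. Fits to fewer libraries estimate the spread from fewer samples, and the fit to all libraries uses the same spread per gene for all 4 groups. The median absolute log2 difference between replicates was 0.0871 in vehicle and 0.101 with LAA, but 0.16 with ATRA and 0.155 with LAA+ATRA. The counts for LAA against vehicle and for LAA+ATRA against ATRA are therefore not on an equal footing. The numbers of the replicates gave no pairing, since correlations of replicate differences between groups ran from -0.073 to 0.077.

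The number of lists called was 0 with an estimated correlation in all 6 comparisons, where, by construction, the test also takes its degrees of freedom from the 8 libraries and not from the genes. For LAA+ATRA against ATRA (5 reported) it was 2 with fry, 14 with the length and GC correction and 4 to 14 without 1 library, and for the interaction (8) 0 with fry and 2 to 12 without 1 library. The glycolysis list in the interaction had an adjusted p from 1.17e-06 to 0.933 without 1 library, and changed direction without LAA+ATRA replicate 2. The cause was not tested.

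At a mean of at least 10 CPM, Pearson's r and Spearman's rho of the LAA effects with and without ATRA were 0.524 and 0.656 (0.177 and 0.394 over all genes) and those of the ATRA effects 0.941 and 0.932 (0.733 and 0.8). The cause was not tested. RLE gave 2 genes called in both LAA comparisons (1 reported). With DESeq2, 444 genes were called in the same direction for LAA and LAA+ATRA against vehicle (4 reported) and 274 for ATRA and LAA against vehicle (3).

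Of 124 fold changes of genes named in the report, none changed sign past the threshold in any alternative. All 124 kept their side with RLE, 118 without the filter, 117 with the block, 120 with the length and GC correction, 108 of 114 with DESeq2, 100 of 113 with only the libraries compared and all but 17 of 118 on FPKM at either pseudocount. Of 992 values without 1 library, 929 kept their side. Depth limits genes with few counts, such as RARB with LAA, and list members near 0.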
